A study of Mus musculus with 41 samples.

How the data were processed

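RNA was measured in the soft tissue of the cochlear duct of CBA/CaJ mice, a strain that keeps its hearing for much of its life and loses it slowly with age. Both cochleae of 1 mouse made 1 sample, and each sample was hybridised to 1 Affymetrix MOE430A array, a 1-colour oligonucleotide array. The labels give 41 arrays in 4 groups by hearing status, namely 9 young control, 17 middle-aged, 9 mild presbycusis and 6 severe presbycusis mice. Presbycusis is hearing loss of old age, so both groups with that label are taken as old here. The hearing-status labels of these groups do not themselves state an age. Age and hearing loss thus could not be separated in comparisons with younger groups. The design text counts 40 arrays with 8 young controls, whereas the labels give 9. All 9 were used, because each had its own values and its own label.

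The deposited value table holds log2 values. The authors' sheet of values per array holds the RMA signal on a linear scale, from Expression Console per the file headers. The log2 table equals the log2 of that signal for every mouse, with a largest difference of 5.07e-05. RMA is a summary of the probes of a probe set. The background and quantile steps and the software version are not stated. A further table of the authors gives a ratio of each older group to young controls. The ratio equals the geometric mean of the group over the arithmetic mean of the 9 young control arrays, and 11 probe sets have no ratio. The signal ranged from 151 to 44507, and the log2 values from 7.24 to 15.44. The median of an array lay between 10.38 and 10.49, so the arrays were on 1 scale. What limits the precision was not tested.

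Of 22690 probe sets, 64 controls were left out. Gene symbols came from the annotation columns of the authors' sheet. They were updated through the gene table of the reference, in which the gene numbers of 20819 probe sets were found, and 1434 probe sets took a newer symbol. Where a gene had several probe sets, the one with the highest mean log2 value was kept, which was needed for 5126 genes. The 954 probe sets annotated to several genes and the 484 with no symbol each stayed on their own. This left 14455 tested items, called genes here, of which 13017 had a gene symbol. No filter on dim genes was used. Positions are those of the authors' annotation on the mouse build NCBI 37.

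A linear model with group and sex was fitted over all 41 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes). It gave the 6 differences between groups, an F test over the 4 groups and the difference between males and females. A second model gave the interaction of group and sex. P values were adjusted by the Benjamini-Hochberg method over all genes of a comparison, and a gene was called at an adjusted p under 0.05. A second count also asked for a change of at least 1.5-fold. Changes are log2 values with their standard error (SE), and group means are given with their standard deviation (SD). Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

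The model was tested on simulated data of the same design, with 14455 genes, 200 of them changed, in 5 runs. It recovered 80.2% of genes changed by 0.5 on the log2 scale for middle-aged against young mice, and 75% for mild presbycusis against young mice. It recovered 69% for severe presbycusis against young mice and 68.8% for severe against mild presbycusis. Of genes changed by 1 it recovered 96.4%, 96.4%, 96% and 95.4% in the same order. The false share of its calls was 4.13%, 3.92%, 4.07% and 5.2%. The noise was drawn independently for each gene and array. These rates thus leave out the correlation between genes and the outlying arrays of the real data.

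The groups, the model, 37 gene lists and the rule for naming genes were fixed before the data were examined. In each comparison, the rule takes the 10 called genes with the largest rise and the 10 with the largest fall among genes with 1 symbol. It adds up to 2 members of each list per direction with the smallest p among those called. Where none was called, the 5 genes with the smallest p are given as not passing. In comparisons with young controls the rule adds the 3 GABA receptor subunits with the smallest p and the hair cell genes Slc26a5, Otof and Myo7a. Ocm, also in the rule, was not among the measured genes with 1 symbol. For sex it adds the sex-linked check genes. Genes named outside this rule are marked as chosen after their values were seen.

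Each list was tested with camera, which compares the list's members with all other genes, at its preset correlation between genes of 0.01 and again with a correlation estimated from the data. It was also tested with fry, which asks whether the list's genes move, on balance, in 1 direction. The p values of each test were adjusted over the 37 lists of a comparison. The lists cover GABA and glutamate receptors and their metabolism, serotonin receptors, aquaporins, potassium cycling, cochlear cell types, neurons, myelin, brain, bone, cartilage, muscle, blood and immune cells, complement, antigen presentation, interferon response, chemokines, endothelium, matrix, mitochondria, stress, apoptosis, cell cycle, clock, immediate early and sex-linked genes. They came from general knowledge of the tissue and not from these arrays.

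The alternatives varied the normalization, the filter on dim genes, the probe sets per gene, the variance model, array weights, the covariates and the arrays in the fit, with each array also left out in turn. Other sheets of the authors hold the same values and gave no alternative. After the data were seen, 6 alternatives were added, and the mean change of each list that passed at the preset correlation was taken again with each array left out. It was also taken without severe presbycusis 1 and 2 together and without middle-aged 3 and 8 together, pairs chosen by their levels of neuron and muscle genes. Shared calls were also counted with each comparison fitted on its own 2 groups. The 6 concern letters b, e and R in the array names of the authors' sheet, whose meaning is not stated, 5 arrays with a median correlation with the other arrays under 0.97, and levels of blood, brain, muscle and neuron genes as terms. Distortion product otoacoustic emission amplitudes, the hearing measure of the design text, are not in the files used and were not analysed here. One array, middle-aged 4, did not match its sex label and kept the label it was deposited with.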

Results

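The data are RNA levels of 14455 genes in the soft tissue of the cochlear duct of 41 CBA/CaJ mice, 1 array per mouse. The design text sets GABA receptors in the ageing cochlea as the subject and compares mice by age and hearing. By their labels there were 9 young controls (4 female, 5 male) and 17 middle-aged mice (10 female, 7 male). A further 9 mice had mild presbycusis (4 female, 5 male) and 6 had severe presbycusis (4 female, 2 male). Adjusted p values of single genes are from limma, and changes are log2 values ± SE. Both groups with hearing loss are taken as old, so a difference from younger mice holds age and hearing loss together.

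GABA receptor subunits, the channels and receptors for the inhibitory transmitter GABA, were compared first. Of 21 listed subunits, 17 were measured, and none was called in any of the 6 comparisons between groups, over all genes or adjusted over the list alone. Measured means that the array held a probe set, and whether the signal lay above background was not tested. Mean levels ran from 8.45 for Gabra2 to 14.32 for Gabbr1, most of them below the array medians of 10.38 to 10.49. A subunit that did not pass may thus not have been detected at all. The smallest adjusted p over all genes was 0.439, for Gabrg3. The widest difference from young controls was that of Gabra6, a subunit of cerebellar granule cells, in severe presbycusis, at 1.19 ± 0.75 (adjusted p = 0.697). Its level was 10.07 ± 1.03 (SD, n = 9) in young controls and 11.24 ± 2.07 (SD, n = 6) in severe presbycusis, with 2 of the 6 arrays above all young controls. Gabrr2 differed by 0.14 ± 0.06 and Gabrb2 by 0.09 ± 0.08 in the same comparison, and neither passed. In mild presbycusis the 3 subunits with the smallest p were Gabra2 at -0.06 ± 0.04, Gabrb1 at -0.21 ± 0.26 and Gabrg3 at 0.06 ± 0.08. In middle-aged mice they were Gabrq at -0.10 ± 0.06, Gabrr2 at 0.07 ± 0.05 and Gabrg3 at -0.09 ± 0.07, none of which passed.

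Hair cells are the sensory cells of the cochlea. Of 30 listed hair cell genes, 20 were measured and none was called in any comparison. Whether their signal lay above background was not tested here either. Slc26a5, the motor protein prestin of outer hair cells, differed from young controls by -0.02 ± 0.05 in middle-aged mice, -0.01 ± 0.06 in mild presbycusis and 0.10 ± 0.06 in severe presbycusis. Otof, needed for transmitter release by inner hair cells, differed by -0.05 ± 0.07, -0.13 ± 0.08 and -0.05 ± 0.09 in the same order. Myo7a, a myosin of the hair bundle, differed by 0.02 ± 0.07, -0.01 ± 0.08 and 0.07 ± 0.09. None of the 9 differences passed.

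Middle-aged mice were set against young controls, a difference in age between mice not labelled with presbycusis. No gene was called, with 254 genes at an unadjusted p under 0.05. The 5 genes with the smallest p, none of which passed, were Crym (crystallin mu, a thyroid hormone binding protein) at -0.45 ± 0.10 (adjusted p = 0.735, lower than the mean of young controls in 16 of 17 mice), Col1a2 (type I collagen) at -0.55 ± 0.13, Mpeg1 (a pore-forming protein of macrophages) at 0.46 ± 0.12, Tenm3 at -0.46 ± 0.12 and Wnt4 at -0.48 ± 0.13. Of the 37 lists, 5 passed at the preset correlation and none with an estimated correlation or by fry. The 26 macrophage and monocyte genes had a mean change of 0.11 (adjusted p = 0.416 with an estimated correlation), and the 15 complement genes of 0.09 (adjusted p = 0.416 with an estimated correlation). The interferon response genes had a mean change of 0.08 and the skeletal muscle genes of 0.20 (adjusted p = 0.845 with an estimated correlation for each). The collagen and matrix genes had a mean change of -0.07 (adjusted p = 0.646 with an estimated correlation), with 1 of 30 lower when adjusted over the list alone. The mean of the muscle genes was 0.02 without middle-aged 8, 0.08 without middle-aged 3, -0.11 without both and 0.34 without young control 4. That of the interferon response genes was 0.05 without young control 2 and 0.13 without young control 8. In the 9 arrays marked b alone the interferon, macrophage, complement and muscle means were -0.37, -0.04, -0.02 and -0.40. Only 1 of these arrays, young control 8, is a young control, so these values rest on that mouse. In arrays with no letter the muscle mean was -0.02. With array weights 1 gene was called.

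Mild presbycusis was compared with young controls. Genes of macrophages, the phagocytes of the tissue and of the blood, rose together: 14 of the 26 macrophage and monocyte genes were higher and none lower, and 19 were higher when adjusted over the list alone. Mpeg1 (chromosome 19, 12535269 to 12539775), a macrophage gene that is not in the list, went from 11 ± 0.25 (SD, n = 9) to 12.55 ± 0.35 (SD, n = 9). This was a rise of 1.55 ± 0.14 or 2.92-fold, with 9 of 9 mice above all young controls (adjusted p = 1.62e-09). Ctss, the lysosomal protease cathepsin S, rose 2-fold and Cd68, a lysosomal protein of phagocytes, rose 2.3-fold. Clec7a, a receptor for fungal glucans, rose 2.4-fold, Laptm5, a lysosomal membrane protein of blood cells, 2.49-fold, and Lyz2, the lysozyme of myeloid cells, 3.34-fold. Ms4a7 rose 1.57-fold.

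Across all genes, 54 were called in mild presbycusis against young controls, 49 higher and 5 lower, and 32 of them changed at least 1.5-fold. Beside the macrophage genes, the named rises were Jchain, the joining chain of immunoglobulins (2.15 ± 0.48), Csn3, the milk protein kappa casein (1.78 ± 0.31, higher than the mean of young controls in 8 of 9 mice), Ptprc, the antigen CD45 of white blood cells (1.26 ± 0.30), Lgals3, a galactose-binding lectin (1.21 ± 0.29, a call lost in 31 of the 41 fits that leave out 1 array), and Lyz1 (1.14 ± 0.20). Lyz1 lay near the top of the scale, where a rise reads too small, and its probe set and those of Laptm5, H2-Aa and H2-K1 are of a kind that is not unique to 1 transcript. The 5 falls were Npnt, the matrix protein nephronectin (-0.94 ± 0.21), Ccnd2, cyclin D2 (-0.90 ± 0.18), Crym (-0.50 ± 0.11), Uros, an enzyme of haem synthesis (-0.35 ± 0.08), and 1500002F19Rik, chosen after its values were seen. Of the 4 other probe sets for Npnt, 2 went down and 2 did not.

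Immune lists were examined in the same comparison. Of 15 complement genes 3 were higher, including C1s1 (0.58 ± 0.13) and C1qc (0.46 ± 0.10), and 4 when adjusted over the list alone (adjusted p = 0.00422 with an estimated correlation), and the list shares 3 members with the macrophage list. Of 16 antigen presentation genes 2 were higher, H2-Aa (0.86 ± 0.19) and H2-K1 (0.40 ± 0.08), and 4 when adjusted over the list alone (adjusted p = 0.0244 with an estimated correlation). The macrophage list had a mean change of 0.56 (adjusted p = 2.07e-08 with an estimated correlation). Of 27 chemokine, cytokine and adhesion genes none was higher and 1 was when adjusted over the list alone (adjusted p = 0.0548 with an estimated correlation). Of 30 interferon response genes none was called in either way, with a mean change of 0.20 (adjusted p = 0.113 with an estimated correlation). In the 9 arrays marked b alone, with 1 young control, the mean of the interferon genes was -0.43, a value that rests on that mouse. Il7r was the 1 T and NK cell gene that rose (0.56 ± 0.13; adjusted p = 0.479 for the list with an estimated correlation), and with the dimmer genes left out the list had a mean change of -0.13.

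Lists of other cells gave the values that follow. Of 20 neutrophil and granulocyte precursor genes 1 was higher, Mmp9, a gelatinase (0.34 ± 0.08, a call lost in 32 of the 41 fits that leave out 1 array), and 9 when adjusted over the list alone, with a mean change of 0.56 (adjusted p = 0.0545 with an estimated correlation). Of 18 erythroid genes none was called in either way, with a mean change of 0.30 (adjusted p = 0.113 with an estimated correlation), and of 27 skeletal muscle genes none was, with a mean change of 0.65 (adjusted p = 0.286 with an estimated correlation). The B and plasma cell list had 1 of 20 higher over all genes and alone, Jchain (adjusted p = 0.451 with an estimated correlation). The 28 proliferation genes had none higher and 1 when adjusted over the list alone (adjusted p = 0.17 with an estimated correlation), and their mean turned to -0.02 with the dimmer genes left out and with blood cell levels as terms. Of 22 immediate early genes, which respond within minutes to a stimulus, none was higher and 3 were when adjusted over the list alone (adjusted p = 0.0572 with an estimated correlation). The 28 neuron genes (adjusted p = 0.507 with an estimated correlation), 16 cartilage genes (adjusted p = 0.0822 with an estimated correlation) and 10 fibrocyte genes of the spiral ligament and limbus (adjusted p = 0.0761 with an estimated correlation) had negative mean changes of -0.18, -0.11 and -0.16 with no member called in either way. That of the neuron genes was -0.09 without mild presbycusis 9, -0.27 without young control 9 and 0.07 with blood cell levels as terms. Htr2b, a serotonin receptor, was the 1 of 13 serotonin receptors higher over all genes and alone (0.47 ± 0.10).

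In all, 15 of the 37 lists passed at the preset correlation in mild presbycusis against young controls, 3 with an estimated correlation (macrophage, complement and antigen presentation) and 6 by fry. The count of 54 genes was 29 with the dimmer genes left out, 2 in females, 20 in males, 12 with the erythroid, neutrophil and B cell levels as terms and 87 without the 5 arrays of low correlation (58 higher and 29 lower). Without young control 4, 9 of the 23 named calls were lost and no direction changed. Of the 41 fits that leave out 1 array, the call was lost in 32 for Mmp9, 31 for Lgals3, 17 for Ptprc, 14 for Il7r, 9 for Uros, 8 for H2-Aa, 7 for C1qc, 6 for Npnt, 5 for Crym, 3 for Jchain and 1 for C1s1, and for the other 12 in none. Losses of Mmp9, Lgals3 and Ptprc also came without arrays of the other 2 groups (18, 19 and 5 fits), which enter through the shared variance and sex terms. In the arrays marked b alone Csn3 turned to -0.15 and Uros to 0.04, against 1 young control, young control 8. That mouse had the highest Csn3 of the young controls, at 11.33 against their mean of 10.4.

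**Figure D1:**
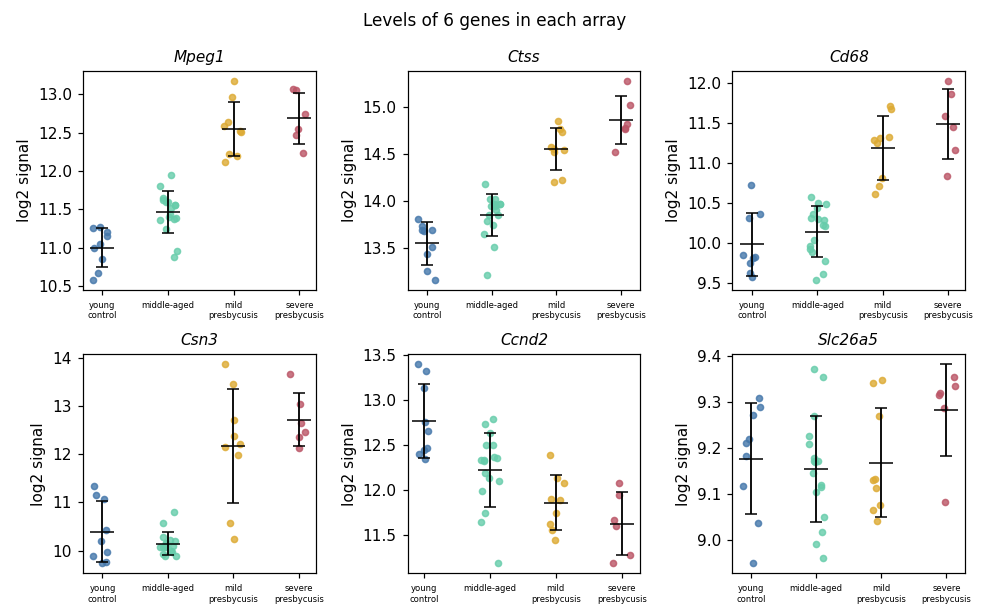
Log2 signal (vertical axis) of 6 genes in each of the 41 arrays by group, with a bar at the group mean and whiskers of 1 SD. Mpeg1 lay near 11 in young controls and 12.55 in mild presbycusis, Ccnd2 near 12.77 and 11.86, and Slc26a5 near 9.18 and 9.17.

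Severe presbycusis was compared with young controls. Macrophage genes were again higher, 15 of 26 over all genes and 21 adjusted over the list alone, with a mean change of 0.73 (adjusted p = 5.33e-08 with an estimated correlation). Mpeg1, which is not in the list, rose 3.22-fold to 12.68 ± 0.33 (SD, n = 6). Of the list, Ctss rose 2.48-fold, Cd68 2.86-fold, Clec7a 2.88-fold, Laptm5 3.13-fold, Lyz2 3.5-fold and Ms4a7 1.78-fold. In Mpeg1, Ctss, Cd68 and Clec7a all 6 mice lay above all young controls. The largest rise was that of Csn3 at 2.38 ± 0.35 or 5.21-fold (chromosome 5, 88354621 to 88359842), in 6 of 6 mice above all young controls.

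In severe presbycusis against young controls 92 genes were called, 69 higher and 23 lower, and 48 changed at least 1.5-fold. Further rises were Lgals3 (1.74 ± 0.33), Clca3a2, a calcium-activated chloride channel regulator (1.51 ± 0.32), Ptprc (1.45 ± 0.34, a call lost without severe presbycusis 2, at 13.23 against 11.385 in the next mouse, and without severe presbycusis 3) and Ms4a6d (1.35 ± 0.17). The 10 largest falls were Cdh2, the adhesion protein N-cadherin (-1.17 ± 0.28), Resp18 (-1.17 ± 0.30), Ccnd2 (-1.15 ± 0.20), Sema5a, a semaphorin (-0.95 ± 0.20), Ywhag, a 14-3-3 protein (-0.90 ± 0.20), Fgf1, a fibroblast growth factor (-0.88 ± 0.17), Gdpd1 (-0.81 ± 0.18), Col1a2 (-0.73 ± 0.17), Tenm3 (-0.63 ± 0.16) and Abhd10 (-0.63 ± 0.14). In each of these 10 genes, 6 of 6 mice lay below the mean of young controls. The other probe sets of Sema5a and Gdpd1 went up, and 1 of 2 other probe sets of Ms4a6d went down. The probe set of Ywhag is of the kind that is not unique to 1 transcript.

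Of the 27 chemokine, cytokine and adhesion genes 5 were higher in severe presbycusis and 7 when adjusted over the list alone (adjusted p = 0.0358 with an estimated correlation), including Cxcl1, which attracts neutrophils (0.90 ± 0.19), and Ccl5, which attracts T cells (0.59 ± 0.12). Of 15 complement genes 3 were higher and 6 adjusted over the list alone, including C1qc (0.77 ± 0.11) and C3ar1 (0.68 ± 0.12; adjusted p = 0.0171 for the list with an estimated correlation). Of 16 antigen presentation genes 2 were higher, H2-Aa (0.97 ± 0.22) and H2-K1 (0.51 ± 0.09), and 7 adjusted over the list alone (adjusted p = 0.0358 with an estimated correlation). Of 30 interferon response genes none was higher and 5 were when adjusted over the list alone, with a mean change of 0.30 (adjusted p = 0.2 with an estimated correlation). In the 9 arrays marked b alone, with 1 young control, their mean was -0.22, a value that rests on that mouse. Il7r (0.66 ± 0.15) and Ccl5 were the 2 of 23 T and NK cell genes that were higher (adjusted p = 0.394 with an estimated correlation), and with the dimmer genes left out the list had a mean change of -0.18. Htr2b rose by 0.74 ± 0.11 (adjusted p = 0.574 for the 13 serotonin receptors with an estimated correlation).

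The 28 neuron genes had a mean change of -0.47 in severe presbycusis, with none called over all genes and 3 lower when adjusted over the list alone (adjusted p = 0.203 with an estimated correlation). Without severe presbycusis 1 and 2 together the mean change was -0.23. The 18 myelin and Schwann cell genes had a mean change of -0.17, with 2 lower when adjusted over the list alone (adjusted p = 0.256 with an estimated correlation). Their mean turned to 0.01 in males, of whom 2 had severe presbycusis, and to 0.05 with brain, muscle and neuron levels as terms. The 10 fibrocyte genes had a mean change of -0.11, with 1 lower when adjusted over the list alone (adjusted p = 0.203 with an estimated correlation). Other lists had mean changes of 0.47 for the neutrophil genes (adjusted p = 0.256 with an estimated correlation), 0.31 for the erythroid genes (adjusted p = 0.288 with an estimated correlation), 0.18 for the B and plasma cell genes (adjusted p = 0.394 with an estimated correlation) and 0.14 for the proliferation genes (adjusted p = 0.427 with an estimated correlation). Of these 4 lists, 1 erythroid gene was higher when adjusted over the list alone and no member was called over all genes. Without severe presbycusis 2 the mean was 0.25 for the neutrophil, 0.11 for the erythroid, 0.12 for the B and plasma cell, 0.04 for the proliferation, -0.11 for the myelin and -0.06 for the fibrocyte genes. Of these 6 lists only the neutrophil list then passed at the preset correlation. The proliferation mean turned to -0.02 with the dimmer genes left out and to -0.004 with blood cell levels as terms. In bone cells and in collagens and matrix, Col1a2 was the 1 gene that fell.

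Of the 37 lists, 14 passed at the preset correlation in severe presbycusis against young controls, 4 with an estimated correlation (macrophage, complement, antigen presentation and chemokines) and 5 by fry. The count of 92 was 46 without severe presbycusis 3, at which 13 of the 31 named calls were lost, 162 without young control 9, 308 without the 5 arrays of low correlation (140 higher and 168 lower), 370 with array weights (163 higher and 207 lower) and 165 with the first residual component as a term (94 higher and 71 lower). The excess of rises in the 92 thus turned in 2 of these settings. It was 41 with the dimmer genes left out, 31 in the 2 groups alone, 31 in females and 12 in males (2 with severe presbycusis). It was 33 in the arrays with no letter, and 33 with either set of other-tissue levels as terms. Of the 41 fits that leave out 1 array, the call was lost in 30 for Resp18, 20 for Tenm3, 10 for Cdh2, 7 for Col1a2 and 3 for Abhd10 (young control 2 and severe presbycusis 2 and 3). It was lost without severe presbycusis 3 for Ptprc, Gdpd1, Lyz2, Ywhag, H2-Aa, Clca3a2 and Cxcl1, without severe presbycusis 2 for Ptprc, Gdpd1, Il7r and Sema5a, without severe presbycusis 1 for Lyz2 and Ywhag, and without severe presbycusis 4 for H2-Aa.

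**Figure D2:**
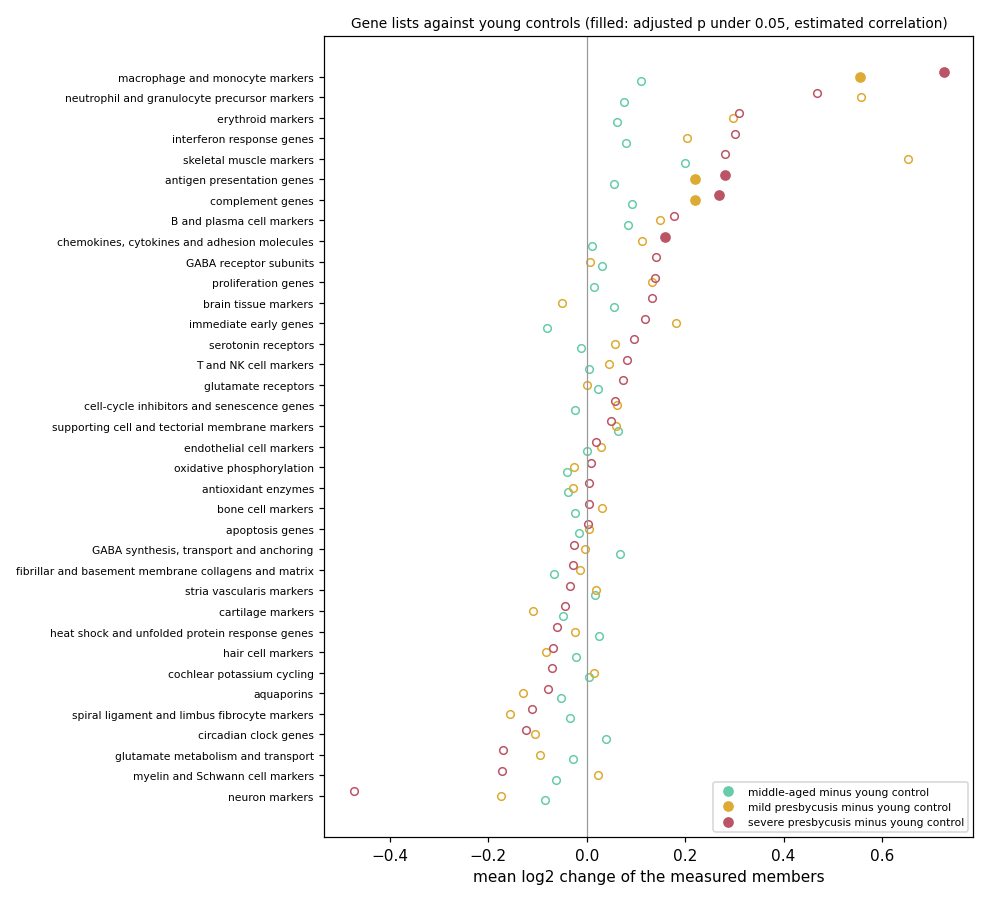
Mean log2 change of the measured members of 36 gene lists (horizontal axis) in each older group against young controls, filled where the list passed with an estimated correlation between genes. The macrophage list had 0.11, 0.56 and 0.73 in middle-aged, mild and severe presbycusis mice, and the neuron list -0.09, -0.18 and -0.47, never filled.

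Mild presbycusis was compared with middle-aged mice, a difference in age and in hearing status. All 30 called genes were higher, and 15 of them changed at least 1.5-fold. The named genes were led by Csn3 (1.98 ± 0.27), Lgals3 (1.38 ± 0.26), Mpeg1 (1.08 ± 0.12, 9 of 9 mice above all middle-aged mice), Clca3a2 (1.08 ± 0.25, a call lost in 26 of the 41 fits that leave out 1 array), Cd68 (1.04 ± 0.15) and Clec7a (1.03 ± 0.14). Laptm5, Clec4d, Fcgr3 and Ms4a6d rose between 1.69-fold and 1.89-fold. Of 26 macrophage genes 8 were higher and 20 adjusted over the list alone, with a mean change of 0.44 (adjusted p = 6.99e-08 with an estimated correlation).

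Of 22 immediate early genes none was called against middle-aged mice and 8 were higher when adjusted over the list alone, with a mean change of 0.26 (adjusted p = 0.00268 with an estimated correlation). Of 16 antigen presentation genes 3 were higher when adjusted over the list alone (adjusted p = 0.0467 with an estimated correlation). One complement gene was higher, C1qc (0.41 ± 0.09), and 3 when adjusted over the list alone (adjusted p = 0.0541 with an estimated correlation). Of the neutrophil genes Mmp9 was higher (0.32 ± 0.07) and 9 were when adjusted over the list alone (adjusted p = 0.0541 with an estimated correlation). Htr2b rose by 0.42 ± 0.09 (adjusted p = 0.32 for its list with an estimated correlation). The 14 cell-cycle inhibitor and senescence genes had a mean change of 0.09 (adjusted p = 0.0814 with an estimated correlation). Chemokines and fibrocyte genes had mean changes of 0.10 and -0.12 (adjusted p = 0.0814 with an estimated correlation for each), interferon genes of 0.13 and collagens of 0.05 (adjusted p = 0.32 with an estimated correlation for each), and cartilage and proliferation genes of -0.06 and 0.12 (adjusted p = 0.173 with an estimated correlation for each). Clock genes had a mean change of -0.15 (adjusted p = 0.128 with an estimated correlation), erythroid genes 0.24 (adjusted p = 0.182 with an estimated correlation), muscle genes 0.45 (adjusted p = 0.411 with an estimated correlation) and T and NK cell genes 0.04 (adjusted p = 0.414 with an estimated correlation). Without mild presbycusis 2 the mean was 0.08 for the interferon and 0.02 for the T and NK cell genes. It was 0.01 for the collagens without mild presbycusis 1, -0.04 for the cartilage genes without mild presbycusis 5, and 0.29 for the muscle genes without mild presbycusis 1 or without mild presbycusis 6. Without middle-aged 3 and 8 together the mean of the muscle genes was 0.77. The means turned to -0.06 for T and NK cell and -0.01 for proliferation genes with the dimmer genes left out, to -0.01 for proliferation genes with blood cell levels as terms and to -0.05 for interferon genes in the arrays marked b alone, none passing. Adjusted over the list alone, 2 chemokine, 2 collagen and matrix and 1 interferon genes were higher and 2 clock and 1 fibrocyte genes lower, none of which was called over all genes. In all 17 lists passed at the preset correlation, 3 with an estimated correlation and 5 by fry.

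The count of 30, all higher, was 47 with array weights (44 higher and 3 lower), 63 without the 5 arrays of low correlation (51 higher and 12 lower), 45 with the first residual component (43 higher and 2 lower), 16 in males, 13 with the blood cell levels as terms, 11 with the dimmer genes left out, 6 in the arrays with no letter and 0 in females. Without middle-aged 5 or 7 or mild presbycusis 2 or 6, each left out alone, 4 of the 15 named calls were lost. Of the 41 fits that leave out 1 array, the call was lost in 26 for Clca3a2, 17 for Mmp9, 7 for C1qc and 2 for Htr2b (mild presbycusis 2 and 6).

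Severe presbycusis was compared with middle-aged mice. Of 106 called genes 65 were higher and 41 lower, and 43 changed at least 1.5-fold. Csn3 was 6-fold higher (2.59 ± 0.31), Lgals3 3.77-fold, Clca3a2 2.74-fold, Cd68 2.55-fold, Clec7a 2.45-fold, Laptm5 2.37-fold, Mpeg1 2.33-fold, Fcgr3 2.16-fold and Ms4a6d 2.11-fold. Of 26 macrophage genes 14 were higher and 23 adjusted over the list alone, with a mean change of 0.62 (adjusted p = 4.88e-07 with an estimated correlation), the 1 list that passed with an estimated correlation. Fos, an immediate early transcription factor, was 2.72-fold higher (1.44 ± 0.34), the 1 of 22 immediate early genes called (adjusted p = 0.268 for the list with an estimated correlation).

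The largest falls against middle-aged mice were Cdh2 (-1.22 ± 0.25, 6 of 6 mice below all middle-aged mice), Aass, an enzyme of lysine breakdown (-1.19 ± 0.25), Rgs4, a regulator of G protein signals (-1.04 ± 0.19), Ywhag (-0.85 ± 0.18), Pfkl, liver phosphofructokinase (-0.84 ± 0.21), Fgf1 (-0.75 ± 0.15), Srsf7, a splicing factor (-0.75 ± 0.16), Acss2, acetyl-CoA synthetase (-0.66 ± 0.16), Gdpd1 (-0.66 ± 0.16) and Ptger3, a prostaglandin receptor (-0.63 ± 0.16). No other probe set of Srsf7 or Ptger3 went down, and 1 of 2 others did for Rgs4 and for Ywhag. Capn2, a calpain (-0.57 ± 0.15), Ndufs1 of respiratory complex I (-0.44 ± 0.11) and Otor, a secreted protein of the cochlea (-0.30 ± 0.07), also fell. Each was the 1 member called of its list, the 43 apoptosis, 63 oxidative phosphorylation and 10 fibrocyte genes.

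Of 27 chemokine genes 4 were higher and 5 adjusted over the list alone, including Ccl5 (0.56 ± 0.11) and Cxcl2 (0.34 ± 0.06; adjusted p = 0.125 for the list with an estimated correlation). Of 15 complement genes 3 were higher and 5 adjusted over the list alone, including C1qc (0.72 ± 0.10) and C3ar1 (0.55 ± 0.11; adjusted p = 0.154 with an estimated correlation). H2-K1 was the 1 of 16 antigen presentation genes higher, with 7 adjusted over the list alone (adjusted p = 0.125 with an estimated correlation). Htr2b rose by 0.69 ± 0.10 (adjusted p = 0.414 for its list with an estimated correlation). Neuron genes had a mean change of -0.39, with 3 lower when adjusted over the list alone (adjusted p = 0.353 with an estimated correlation). Clock genes had a mean of -0.16 and a median of 0.01, with 6 of 16 lower when adjusted over the list alone (adjusted p = 0.268 with an estimated correlation). Interferon genes had a mean change of 0.22 with 3 higher adjusted over the list alone, neutrophil genes of 0.39 and heat shock genes of -0.08 (adjusted p = 0.361 with an estimated correlation for each of the 3 lists). Erythroid genes had a mean change of 0.25 and T and NK cell genes of 0.08 with Ccl5 higher, and 2 adjusted over the list alone (adjusted p = 0.37 with an estimated correlation for each), and proliferation genes of 0.12 (adjusted p = 0.432 with an estimated correlation). With the dimmer genes left out the mean turned to -0.105 for T and NK cell and -0.01 for proliferation genes. It turned in males, of whom 2 had severe presbycusis, to -0.01 for erythroid, -0.004 for neutrophil and -0.03 for proliferation genes. In arrays with no letter it turned to -0.02 for erythroid and -0.03 for proliferation genes, and none of these passed. Without severe presbycusis 2 the mean was 0.17 for the neutrophil, 0.04 for the erythroid and 0.03 for the proliferation genes, and none of the 3 then passed at the preset correlation. The mean of the neuron genes was -0.14 without severe presbycusis 1 and 2 together, and that of the heat shock genes ran from -0.12 without middle-aged 1 to -0.05 without middle-aged 9. In all 14 lists passed at the preset correlation and 5 by fry.

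The count of 106 was 51 without severe presbycusis 3, at which 11 of the 32 named calls were lost, 67 without severe presbycusis 1, 171 without middle-aged 1, 258 without the 5 arrays of low correlation (125 higher and 133 lower), 365 with array weights (166 higher and 199 lower) and 278 with the first residual component (128 higher and 150 lower). It was 69 with the dimmer genes left out (27 higher and 42 lower), so that falls outnumbered rises in these 4 settings. The first residual component comes from the residuals of the same model and takes spread out by construction. Its larger count is therefore no evidence on the calls. It was 31 in females, 10 in males (2 with severe presbycusis) and 20 in arrays with no letter. It was 52 with brain, muscle and neuron levels and 47 with blood cell levels as terms. Of the 41 fits that leave out 1 array, the call was lost in 25 for Capn2, 17 for Ptger3, 9 for Pfkl, 6 for Acss2, 4 for Fos (severe presbycusis 1, 3, 5 and 6) and 4 for Ndufs1 (middle-aged 14 and severe presbycusis 1, 3 and 4). It was lost in 3 for Otor (severe presbycusis 2, 3 and 6) and Gdpd1 (severe presbycusis 2, 3 and 4), in 2 for Srsf7 (severe presbycusis 1 and 3), and in 1 for Ywhag (severe presbycusis 1), Aass (severe presbycusis 3) and H2-K1 (severe presbycusis 4).

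Severe was compared with mild presbycusis, the comparison of hearing loss within old mice. No gene was called by limma, with 503 at an unadjusted p under 0.05. The 5 with the smallest p, none of which passed, were Mapre2, a microtubule end protein (-0.61 ± 0.12, adjusted p = 0.256, 6 of 6 severe below all mild), Ywhag (-0.83 ± 0.20), Folh1 (0.37 ± 0.10), Kctd9 (-0.42 ± 0.12) and a probe set annotated to both Gm9923 and Hbs1l (-0.29 ± 0.08). The macrophage genes had a mean change of 0.17 (adjusted p = 0.191 with an estimated correlation), the myelin genes of -0.20 (adjusted p = 0.243 with an estimated correlation), the neuron genes of -0.30 (adjusted p = 0.801 with an estimated correlation) and the muscle genes of -0.37 (adjusted p = 0.872 with an estimated correlation). These 4 lists passed at the preset correlation, none with an estimated correlation or by fry, and no member was called in either way. In males, of whom 2 had severe presbycusis, the mean was 0.03 for the neuron and 0.01 for the myelin genes. There the macrophage list lost its call at 0.10. The muscle list lost its call in females at -0.07, with array weights at -0.18 and with the dimmer genes left out at -0.42. In arrays with no letter the mean was 0.25 for the muscle genes, and the neuron and myelin lists lost their calls at -0.13 and -0.11. The myelin list also lost its call with brain, muscle and neuron levels as terms at -0.08. The mean of the muscle genes was -0.20 without mild presbycusis 1, -0.22 without mild presbycusis 6, -0.23 without severe presbycusis 5 and -0.62 without severe presbycusis 6. That of the neuron genes was -0.19 without severe presbycusis 1 and -0.06 without severe presbycusis 1 and 2 together. The count was 1 without young control 9 and 1 without the 5 arrays of low correlation.

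The calls were also compared between pairs of comparisons that have no group in common. All comparisons came from 1 model over the 41 arrays, with shared variance and sex terms, so the calls are not independent. Of the 49 genes higher in mild presbycusis against young controls and the 65 higher in severe presbycusis against middle-aged mice, 30 were the same genes. Of the 69 higher in severe presbycusis against young controls and the 30 higher in mild presbycusis against middle-aged mice, 22 were the same. Among the lower genes, Uros was the 1 shared by the 5 and the 41 of the first pair. With each comparison fitted on the arrays of its own 2 groups, so that no array was in both fits, 19 of 36 and 87 higher genes were the same in the first pair and 15 of 28 and 33 in the second. Independent draws from the 14455 genes would give 0.22 and 0.064, a comparison that leaves out the correlation between genes. Both of these sets held Mpeg1, Ctss, Cd68, Clec7a and Laptm5, only the second held Csn3 and Htr2b, and neither held Lgals3 or any lower gene. The F test called 108 genes over the 4 groups, and between 0 (the 9 arrays marked b alone) and 274 (array weights) in the settings tried.

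**Figure D3:**
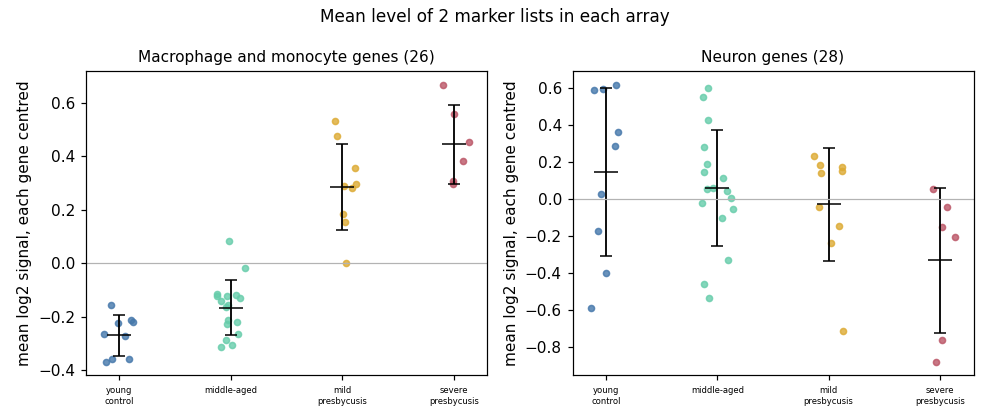
Mean log2 signal of the 26 macrophage and 28 neuron genes in each array (vertical axis, each gene centred on its mean), with the group mean and whiskers of 1 SD. The macrophage mean ran from -0.37 to -0.15 in young controls and from 0.30 to 0.67 in severe presbycusis.

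Of the 37 lists, 16 passed in none of the 6 comparisons at the preset correlation. They were the antioxidant, apoptosis, aquaporin, bone cell, brain, potassium cycling, endothelial, GABA receptor, GABA synthesis and transport, glutamate metabolism, glutamate receptor, hair cell, oxidative phosphorylation, sex-linked, stria vascularis and supporting cell lists. The 17 genes of the stria vascularis, which makes the endocochlear potential, had mean changes between -0.05 and 0.02. The 17 potassium cycling genes had mean changes between -0.08 and 0.02, and the 63 oxidative phosphorylation genes between -0.04 and 0.05.

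Male and female mice were compared with group as a term. Ddx3y and Eif2s3y, on the Y chromosome, were higher in males by 4.82 ± 0.23 and 3.88 ± 0.24, and Xist, the RNA that silences 1 X chromosome, was lower by -3.32 ± 0.20. The only further call was a probe set annotated to both Eif2s3x, on the X chromosome, and Gm2223, chosen after its values were seen (-0.30, adjusted p = 0.0102). Uty (0.05 ± 0.04) and Kdm5d (-0.07 ± 0.06), both Y-linked, did not pass with the probe sets used, but Kdm5d passed at 0.41 with the mean of its probe sets. The arrays labelled female had Xist between 14.64 and 15.25, except middle-aged 4 at 11.86, and its Ddx3y of 11.13 and Eif2s3y of 11.49 were near those of males. Of the 4 calls, 1 was left with the dimmer genes left out, 7 were made with array weights and 9 among all probe sets. The model called no gene with an interaction of group and sex, with 695 at an unadjusted p under 0.05 and a smallest adjusted p of 0.937, but 1 without middle-aged 15 and 6 in the arrays with no letter.

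**Figure D4:**
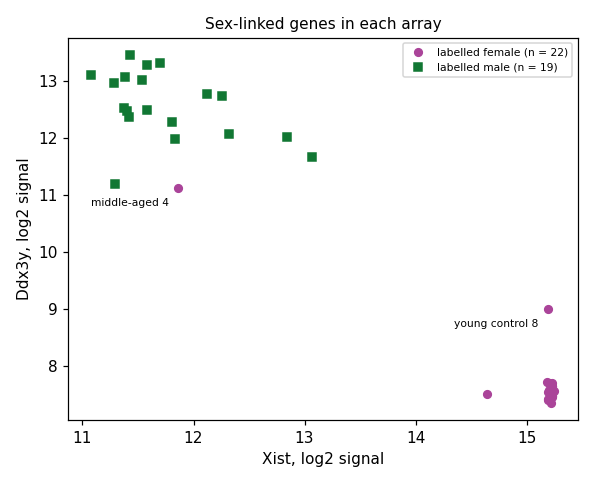
Log2 signal of Xist (horizontal axis) and Ddx3y (vertical axis) in each of the 41 arrays by the sex on its label. The 19 arrays labelled male lay between 11.08 and 13.07 for Xist, and middle-aged 4, labelled female, lay at 11.86.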

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

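The tests of the macrophage genes, of the brain genes against Gabra6 and of the sex of middle-aged 4 were chosen after the results were seen, and only the test of RNA degradation was set before.

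Macrophage and monocyte genes were higher in both presbycusis groups than in young controls, by a mean of 0.56 ± 0.06 (SE) in mild and 0.73 ± 0.06 in severe presbycusis on the log2 scale. Erythroid, neutrophil and B cells carried over from blood or marrow were argued against as the whole cause. With their levels as terms the change was 0.441 ± 0.0552 and 0.633 ± 0.0599, although single-gene counts dropped to 12 and 33. No term followed monocytes, whose genes are in the list itself, so the test cannot decide on monocytes carried over. A batch shown by the letters in the array names was argued against by changes of 0.541 ± 0.0604 and 0.71 ± 0.0695 with the letters as terms. The 19 endothelial genes did not rise as much, at 0.0299 ± 0.0483 and 0.0188 ± 0.0545. They cannot decide on a lower share of the other cells of the tissue, because endothelium is itself 1 of those cells. The hypothesis that macrophages were more numerous, or held more of these RNAs, in old ears with hearing loss stays open and untested. Age and hearing loss cannot be separated here, and 3 of the 26 genes are also complement genes.

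Gabra6 was spread widely between arrays within groups, with a highest value of 15.44 in middle-aged 8 and further high values of 14.49 in severe presbycusis 6 and 13.25 in severe presbycusis 4. Brain tissue carried over in dissection is a candidate explanation: within groups over 41 arrays Gabra6 followed the mean of 13 other brain genes, with r = 0.747 (permutation p = 1.0e-05, the smallest 1e+05 permutations can give, adjusted over 2 relations 2.0e-05) and rho = 0.53 (permutation p = 4.6e-04, adjusted 9.2e-04). Without middle-aged 8 and severe presbycusis 6, r was 0.512, so much of the relation rests on those arrays. RNA degradation was argued against by r = 0.0066 with the difference between the 3' and 5' probe sets of Actb (permutation p = 0.97, rho = 0.081 with permutation p = 0.61). A true difference of Gabra6 in the cochlea was not tested and stays open.

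Middle-aged 4, labelled female, had Xist at 11.86, Ddx3y at 11.13 and Eif2s3y at 11.49, against means of 15.19, 7.62 and 7.51 in the other 21 arrays labelled female and 11.75, 12.57 and 11.54 in the 19 labelled male. A wrong sex label is a candidate explanation, since 3 of 3 genes lay nearer the male mean. A swap with another array of the series was argued against, as 0 of 19 arrays labelled male had the female levels. An equal mixture of a male and a female sample was argued against, as it would put Xist at 14.31, above 11.86 by far more than the SD of 0.541 among males, but a small female share or a swap with a sample outside the series was not excluded. No biological explanation was tested.

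Of 225 sets of a gene or quality value in a group of 4 to 10 arrays, 24 held an array far from the others, and chance gives about 1 in 20. Young control 9 had 4 such values, with Capn2 at 11.646 and Ywhag at 12.974 far below the other young controls, and Clec4d at 10.229 and Gabrq at 10.454 far above. In young control 4, Folh1 was low at 7.8145, Lyz2 was high at 15.148, and the difference between the 3' and 5' probe sets of Gapdh was low at 1.9974. In young control 3, Lgals3 was high at 11.07.

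Mild presbycusis 2 had 4 values apart, with Acss2 low at 10.753 and Gabrq at 10.334, Kdm5d at 10.706 and Uty at 8.8919 high. Mild presbycusis 7 had high values of Cxcl2 at 9.3883 and Mmp9 at 11.332, and mild presbycusis 3 of Gabra6 at 11.671. Low values were Lyz1 at 15.155 in mild presbycusis 4, Otor at 14.561 in mild presbycusis 1 and Sema5a at 9.011 in mild presbycusis 9. Severe presbycusis 2 was high for Jchain at 15.044 and Ptprc at 13.23 and low for Fgf1 at 12.409. Severe presbycusis 4 was high for Gabra2 at 8.6281, and severe presbycusis 6 was high for Otof at 11.334 and low for Slc26a5 at 9.0828.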

How the results depend on the processing

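Of the 20 alternative settings, all but the 6 on array letters, low-correlation arrays and other-tissue levels were planned, and those 6 were chosen after seeing the data. The median of all log2 changes lay within 0.02 of 0 in every comparison, and the floor of the signal, near 7.24, and its top, at 15.44, compress changes of dim and very bright genes. The other sheet of the authors was not run because it holds the same values. Lists whose own level was a term were not tested in that setting, a choice made after the values were seen. The cause of a change between settings was not tested, also where fewer genes or arrays were used.

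Counts that moved by over 1.5 times are given in the order mild and severe presbycusis against young controls, mild and severe against middle-aged mice, and the F test. With the dimmer genes left out they were 29, 41, 11, 69 and 51, with 1 for sex. In females they were 2, 31, 0, 31 and 20, and in males, of whom 2 had severe presbycusis, 20, 12, 16, 10 and 16. With erythroid, neutrophil and B cell levels as terms they were 12, 33, 13, 47 and 37. Without the arrays of low correlation they were 87, 308, 63, 258 and 273, with 1 for severe against mild presbycusis. At least 1.5-fold changes numbered 32, 48, 15 and 43. With array weights the last 4 were 370, 47, 365 and 274, with 1 for middle-aged against young mice and 7 for sex. In arrays with no letter the last 4 were 33, 6, 20 and 40, with 6 for the interaction. For severe presbycusis against young controls, severe against middle-aged mice and the F test they were 33, 52 and 54 with brain, muscle and neuron levels as terms, and 165, 278 and 185 with the first residual component. The 2 groups alone gave 31 for severe presbycusis against young controls, and every probe set on its own gave 9 for sex. The 9 arrays marked b alone, of which only 1 is a young control, gave 0 in all 5, with 1 for sex. The interaction was not run in them, and young control 1, marked with both e and b, was not among them.

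With each array left out in turn, the ranges were 0 to 0 for middle-aged against young mice, 38 to 63 for mild and 46 (without severe presbycusis 3) to 162 (without young control 9) for severe presbycusis against young controls. They were 22 to 41 for mild and 51 (without severe presbycusis 3) to 171 (without middle-aged 1) for severe presbycusis against middle-aged mice, with 67 without severe presbycusis 1. They were 0 to 1 (without young control 9) for severe against mild presbycusis, 78 to 144 for the F test, 4 to 6 for sex and 0 to 1 (without middle-aged 15) for the interaction.

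Of 2598 values of 134 named gene results, 2094 kept direction and side of the threshold, 498 lost the call, 3 gained it and 3 changed sign. These were Kdm5d in males against females at 0.41 for the mean of its probe sets, which disagree, and Csn3 at -0.15 and Uros at 0.037 in mild presbycusis against young controls. The values of Csn3 and Uros came from the arrays marked b alone, with 1 young control. Of 1362 values of 69 list results, 1148 kept both, 184 lost the call and 30 changed sign. The 69 were calls at the preset correlation, and the settings tested them again at that correlation only. With an estimated correlation, 0, 3 and 4 lists passed for middle-aged, mild and severe presbycusis mice against young controls. It was 3 and 1 for mild and severe presbycusis against middle-aged mice, and 0 for severe against mild presbycusis. With other variance models, every probe set on its own or the first residual component as a term, the changes themselves cannot move. There the direction was kept by construction, and only the p values could differ. The first residual component was taken from the residuals of the same model, so it removes spread by construction. Its larger counts are therefore no evidence on the calls. The macrophage list kept its call in all 20 settings in the 4 comparisons of presbycusis with younger mice, with a mean change from 0.384 to 0.743 for mild and 0.633 to 0.95 for severe presbycusis against young controls. In males alone, of whom 2 had severe presbycusis, it was lost for middle-aged against young mice (0.0741) and for severe against mild presbycusis (0.0957). Both were calls at the preset correlation only, and with an estimated correlation neither passed in all arrays (adjusted p = 0.416 and 0.191).

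The sign changes with the dimmer genes left out, in the order mild and severe against young controls and mild and severe against middle-aged mice, were -0.132, -0.177, -0.0602 and -0.105 for T and NK cell genes and -0.0207, -0.0195, -0.00757 and -0.00635 for proliferation genes. With blood cell levels as terms proliferation genes gave -0.0181, -0.004 and -0.00975 in the first 3 of these, and neuron genes 0.0707 in the first. In severe presbycusis against young controls myelin genes gave 0.013 in males and 0.0462 with brain, muscle and neuron levels as terms. In severe presbycusis against middle-aged mice, males gave -0.0107 for erythroid, -0.00383 for neutrophil and -0.0261 for proliferation genes, and arrays with no letter -0.0249 for erythroid and -0.0259 for proliferation genes. In severe against mild presbycusis, males gave 0.0274 for neuron and 0.00504 for myelin genes, and arrays with no letter 0.246 for muscle genes. The values of males with severe presbycusis rest on 2 mice. Arrays with no letter gave -0.023 for muscle genes in middle-aged against young mice. In middle-aged against young mice the arrays marked b alone gave -0.0356 for macrophage, -0.0216 for complement, -0.373 for interferon and -0.4 for muscle genes. For interferon genes these arrays also gave -0.426 in mild and -0.218 in severe presbycusis against young controls, and -0.0533 in mild presbycusis against middle-aged mice. Their values against young controls rest on 1 mouse, young control 8.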

Other observations

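The counts of other splits of the arrays were planned, and the other values of this part were chosen after the data were seen.

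Hormone genes of the pituitary were measured at high levels in some arrays. Prl, prolactin, reached 15.44 in young control 1, young control 3 and middle-aged 13, 14.87 in middle-aged 10, 14.82 in mild presbycusis 2, 13.31 in middle-aged 9 and 12.77 in middle-aged 12, with group medians of 11.57 in young controls, 11 in middle-aged mice, 10.53 in mild and 10.45 in severe presbycusis. Gh, growth hormone, reached 14.86 in young control 1, 14.07 in middle-aged 13 and 13.44 in young control 3. The authors' ratio to young controls was 0.273, 0.197 and 0.125 for Prl and 0.310, 0.229 and 0.209 for Gh in middle-aged, mild and severe presbycusis mice. Because this ratio sets a geometric mean over an arithmetic one, 28, 24 and 30 probe sets have a ratio under 0.25 in the 3 groups, against 0, 0 and 2 with a geometric mean of young controls. With geometric means on both sides the ratios were 0.715, 0.515 and 0.326 for Prl and 0.6, 0.442 and 0.404 for Gh, and 2 of the young controls lay at the top of the scale for Prl. Csn3 was low in middle-aged mice, at 10.15 ± 0.24 (SD, n = 17), and ran from 10.25 to 13.87 in the 9 mice with mild presbycusis. The authors' ratio was 0.772, 3.14 and 4.57 for Csn3 and 1.36, 2.88 and 3.17 for Mpeg1, against 0.844, 3.43 and 4.99 and 1.38, 2.92 and 3.21 with geometric means.

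Some arrays stood apart in genes of other tissues. The mean level of 27 skeletal muscle genes, each centred, was 2.37 in middle-aged 8, 2.04 in middle-aged 3, 1.79 in mild presbycusis 6, 1.504 in mild presbycusis 1 and 1.26 in severe presbycusis 6. Young control 8, labelled female, had Ddx3y at 9.01, Xist at 15.19 and Eif2s3y at 7.71. The median correlation with the other arrays was 0.944 for middle-aged 1, 0.958 for young control 4, 0.965 for young control 9, 0.9698 for middle-aged 8 and 0.9696 for severe presbycusis 1.

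Each count of genes was set against 100 splits of the same arrays into groups of the same sizes, the real one included. A share under 0.05, taken for each count alone and not adjusted over the counts, was the bar. It was met for mild presbycusis against young controls (54 genes, 3 splits as large, highest other 165) and for severe presbycusis against young controls (92 genes, 3 splits, highest other 116). It was also met for severe presbycusis against middle-aged mice (106 genes, 3 splits, highest other 887) and the F test (108 genes, 2 splits, highest other 254). Because some random splits gave larger counts, chance was not excluded for these counts. The bar was met with no other split as large for mild presbycusis against middle-aged mice (30 genes, 1 split, highest other 1) and for sex (4 genes, 1 split, highest other 2). For middle-aged against young mice and for severe against mild presbycusis the real count was 0 genes, so all 100 splits were as large by definition (highest other 3) and the splits say nothing about chance. The split with 887 genes put middle-aged 1, 3 and 11 and severe presbycusis 2, 3 and 4 together, and the one with 165 put young control 4, 5, 7 and 9 with mild presbycusis 2 to 6. Counts several times the real one point to a structure of the arrays other than their groups, and what it is was not tested.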
